A study of Homo sapiens with 12 samples.

How the data were processed

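Poly(A)-selected RNA was sequenced from 12 libraries of HCT116 cells, an established human colorectal cancer line. The libraries form 3 groups of 4: empty vector (EV) cells in complete medium, EV cells in serine-deficient medium, and PSAT1 knockout cells in serine-deficient medium, all after 24 h. RNA was extracted on columns, selected with oligo-dT beads and made into libraries with the TotalScript kit, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. The EV titles also carry a library code, running from 39 to 46 without a gap, and the knockout titles carry none. No knockout library in complete medium is among the samples analysed here, so medium and genotype could not be crossed in a model. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

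The deposited values are FPKM, a fragment count scaled to transcript length and to the mapped fragments of the library, with 1 value per gene symbol and library, as made by the authors. STAR, Cufflinks and the hg19 build are named, without versions, per the submitters' processing notes. The annotation, the choice of the genes listed and any scaling between libraries are not given in the sources used here. Each library lists the same 12556 gene symbols, of which 11121 stood at 1 FPKM or more in all 12 libraries, so genes of low expression are largely not covered. The list of RNA quality genes had only 4 measured members, all histone genes, because the mitochondrially encoded genes were not among the symbols used here. FPKM of a gene mixes reads of near-identical copies, so values of ribosomal protein, metallothionein and histone genes and of the pseudogenes IGBP1P1 and PVRIG2P are uncertain, as are those of P2RY11 and PIGY, which overlap other genes. No read counts were used, and the depth is unknown. Small RNA genes whose values differed between 2 libraries by 1 shared ratio gave relative depths for 9 libraries, counting the reference. They ran from 0.843 to 1.1 times that of the reference, EV serine-deficient replicate 1, each other estimate resting on 3 to 5 genes. Only ratios within 0.4 on the log2 scale were considered, so a larger difference in depth could not have been found. No depth could be estimated for EV complete replicates 1 and 2 or knockout replicate 2. No interval or floor that needs counts is given. The sum of FPKM ran from 314154 to 336906.

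Values were analysed as log2(FPKM + 1), and fold changes are on that scale, which understates changes of low genes. Genes with a mean of at least 1 FPKM over the 12 libraries were tested, which kept 11932 and left out 624. A group-means model was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 3 contrasts were serine-deficient against complete medium in EV cells, knockout against EV in serine-deficient medium, and knockout in serine-deficient medium against EV in complete medium. "Rose" and "fell" refer to genes past that threshold. Every contrast was also fitted on its own 8 libraries. For PSAT1 an exact two-sided permutation test over the 70 arrangements was added.

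The scripts were tested on simulated data with 200 changed genes among 11932. Noise was drawn for each gene independently, so spread that many genes share within a group was not simulated. The numbers of unchanged genes called below therefore do not measure the error that such shared spread can give. In the medium contrast the 12-library model recovered 67.2% of changes of 0.5 on the log2 scale and 94% of changes of 1, and called 159 of 11732 unchanged genes, against 57 when only the 8 libraries compared were fitted. In the knockout contrast it recovered 65.7% of changes of 0.5 and 91% of changes of 1 and called 1 unchanged gene, and the fit on 8 libraries recovered 97% and 100% and called 16. The EV complete-medium libraries vary more than the others, so the shared estimate of spread is too small for the first contrast and too large for the second. Values from both fits are therefore given.

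In total 23 gene lists with 627 symbols were fixed before the data were examined, as were the tests, the rule for naming genes and most alternatives. Lists with at least 5 measured genes, 20 in all, were tested with camera at its preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation and with fry. The genes named are PSAT1, PHGDH, PSPH, SHMT1 and SHMT2, the 6 largest rises and 6 largest falls of each main contrast among called genes whose groups do not overlap, and for each list the 2 members with the smallest p where the adjusted p passed. Some genes that this rule takes are not reported here, though the counts include them. Any other gene is said to have been chosen after its values were seen.

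The alternatives were other pseudocounts, filters, scalings, thresholds and variance models, fits on 2 groups, a replicate block, and leaving out each library in turn. Added after seeing the data were a fit without EV complete-medium replicates 1, 2 and 3, removal from each library of its smooth trend with transcript length and GC content (natural splines with 4 degrees of freedom each), and the library code as a covariate. Without those 3 libraries the remaining complete-medium library is assumed to vary like the other groups. Lengths and GC content came from GENCODE v29 transcripts of another genome build, matched by symbol for 98.0% of the genes, and no coordinates are given for that reason. No pair of libraries held identical values, and none was left out of the main fit.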

Results

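RNA of HCT116 colon cancer cells was profiled after 24 h in 3 groups of 4 libraries, to measure how cells respond when serine from the medium, and then also serine made in the cell through PSAT1, is removed. EV cells grew in complete or in serine-deficient medium and PSAT1 knockout cells in serine-deficient medium. PSAT1 encodes phosphoserine aminotransferase, an enzyme of the pathway that makes serine from a glycolytic intermediate. The pathway begins with PHGDH and ends with PSPH. Expression is given as FPKM, mean ± SD over 4 libraries, and no read depth was available.

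The targeted gene was lowest in the knockout libraries. PSAT1 stood at 46.5, 45.8, 47.9 and 48.5 FPKM in the 4 knockout libraries, at 109, 106, 88.4 and 85.5 FPKM in EV cells in serine-deficient medium, and at 105, 129, 191 and 162 FPKM in EV cells in complete medium. The knockout mean was 48.5% of the EV mean in the same medium (log2 fold change -1.02, SE 0.15, limma adjusted p = 0.0041), and all 4 knockout libraries lay below all 4 EV libraries (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements can give). Transcript remained in each knockout library, and an FPKM over the whole gene does not show whether a small deletion is present.

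**Figure D1:**
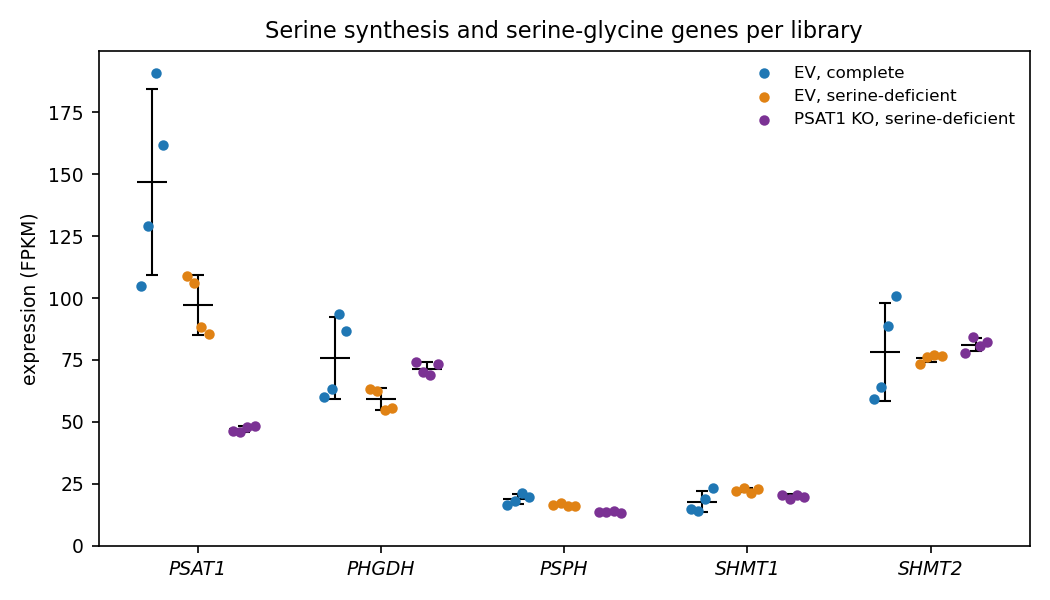
FPKM of PSAT1, PHGDH, PSPH, SHMT1 and SHMT2 per library (dots), with the mean and SD of 4 libraries per group (black bars). PSAT1 lies between 45.8 and 48.5 FPKM in the knockout libraries and at 85.5 FPKM or more in the EV libraries.

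The libraries of EV cells in complete medium differed from each other more than those of the other groups. The first principal component held 74.6% of the variance and placed the 4 complete-medium libraries at -61.29, -55.18, -28.44 and 3.03, the EV serine-deficient libraries between 8.455 and 15.52, and the knockout libraries between 22.38 and 24.02. Spearman correlations within the complete-medium group ran from 0.914 to 0.993, against 0.994 to 0.997 within the EV serine-deficient group and 0.989 to 0.997 within the knockout group. DDIT3, a stress-induced transcription factor, illustrates the spread at 334, 308, 144 and 27.1 FPKM in the complete-medium libraries. For the medium, values without complete-medium replicates 1, 2 and 3 are given beside each gene group. That fit leaves 1 complete-medium library, replicate 4, so its counts and p-values cannot tell the medium from an offset of that library. Relative to the EV serine-deficient mean, replicate 4 had higher medians for mitosis (0.16), replication (0.19), respiratory chain (0.14) and ribosomal protein (0.14) genes. Its medians were lower for nucleolar (-0.05) and histone (-0.66) genes.

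**Figure D2:**
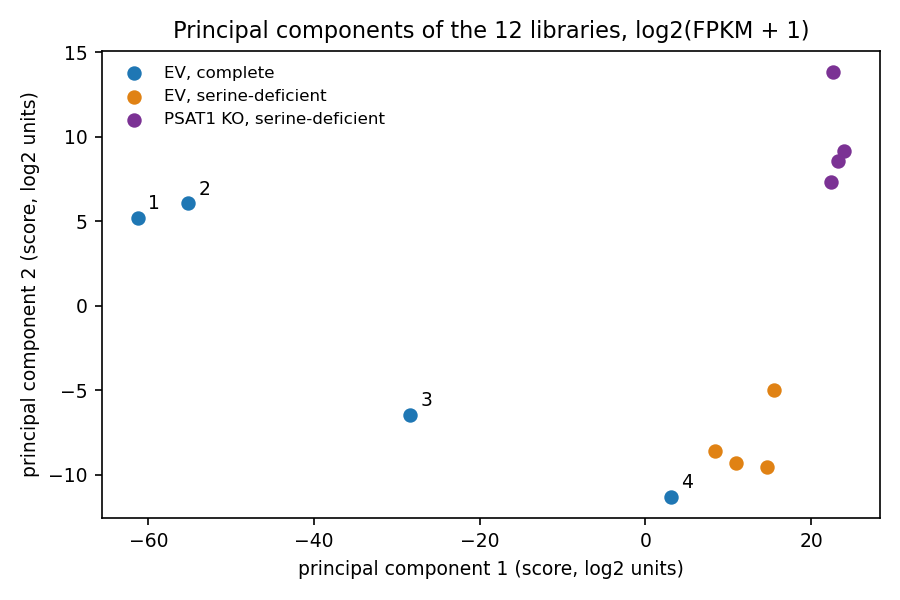
Positions of the 12 libraries on the first 2 principal components of log2(FPKM + 1), one dot per library, with replicate numbers beside the EV complete-medium libraries. Complete-medium replicates 1 to 3 lie between -61.29 and -28.44 on the first component, and the other 9 libraries between 3.03 and 24.02.

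The first comparison asked how EV cells responded to serine-deficient medium. Genes of the amino acid and endoplasmic reticulum stress responses were lower in the libraries labelled serine-deficient than in those labelled complete medium. The spread among the complete-medium libraries was not explained, and an exchange of the 2 whole EV groups was not addressed. These falls can therefore not be tied to the removal of serine. Of 22 measured genes of the integrated stress response, the program driven by the transcription factor ATF4, 19 fell and 1 rose (median log2 fold change -1.04). ASNS, which makes asparagine, went from 260 ± 62.7 to 91.3 ± 11.1 FPKM (log2 fold change -1.48, SE 0.14, adjusted p = 2e-04), and DDIT4, an inhibitor of mTORC1 signalling, from 66.7 ± 19.8 to 17.9 ± 2.33 FPKM (-1.80, SE 0.17). Of 20 endoplasmic reticulum chaperone and unfolded protein response genes 19 fell, among them HSP90B1, from 566 ± 92.8 to 282 ± 13.4 FPKM, and PDIA6, from 108 ± 10.8 to 72.1 ± 2.37 FPKM. With complete-medium replicates 1 to 3 left out, 16 genes of the first list and 15 of the second fell and 1 rose in each, with medians of -0.54 and -0.40. Adjusted over the list alone, 19 fell in each. On the 8 libraries compared 18 of the first and 19 of the second fell.

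The 6 largest falls were those of NGFR (119 ± 102 to 2.97 ± 0.817 FPKM, log2 fold change -4.14), DDIT3 (203 ± 144 to 8.53 ± 1.79 FPKM, -3.93), JUN (-2.74), PCLO (-2.51), CHAC1 (-2.44), which degrades glutathione, and ARRDC4 (-2.43). Their SE lay between 0.28 and 0.79. Without complete-medium replicates 1 to 3 the log2 fold changes were -1.14, -1.58, -0.47, -0.39, -1.50 and -0.93. The 6 largest rises were H2AFX (26 ± 26.8 to 72.5 ± 4.36 FPKM, 1.96), TOMM5 (1.79), MARCKSL1 (1.79), KRTAP2-3 (1.77), PIGY (1.76) and ZBED2 (1.66), and came to 0.16, 0.17, 0.29, 0.80, 0.46 and 0.24 without those libraries.

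Further lists held more falls than rises with all 12 libraries. Of 30 autophagy and lysosome genes 25 fell, among them CTSL (60.5 ± 18.5 to 24.9 ± 1.98 FPKM), whereas 16 fell with quantile normalization, and 8 fell and 1 rose without complete-medium replicates 1 to 3. Of 24 p53 target genes 17 fell, with DDB2 at -0.73, and 2 rose, with PLK2 at 0.36. Without those 3 libraries 6 fell and 6 rose. Of 16 immediate-early genes, which respond within minutes to handling, 14 fell, with EGR1 at -1.63 and ATF3 at -2.35, and 7 fell without the 3 libraries. Of 20 amino acid transporters 9 fell and 2 rose, with SLC3A2 at -0.68 and SLC43A1 at -0.82, and 8 fell and 1 rose without the 3 libraries. SLC7A11, the cystine carrier, went from 22.8 ± 6.6 to 6.99 ± 1.37 FPKM. Of 20 cytosolic aminoacyl-tRNA synthetases 10 fell and 3 rose, with AARS at -1.05 and CARS at -0.55, against 13 and none without them. With median-of-ratios scaling 8 synthetases fell and 6 rose, and the list median went from -0.17 to -0.02. Of 21 interferon-stimulated genes 13 fell and 2 rose, with IFI35 at -0.80 and HERC5 at -0.72. Without the 3 libraries 6 fell and none rose, and the median went from -0.44 to -0.16. Camera did not call the transporters (adjusted p = 0.14), the synthetases (0.14) or the interferon list (0.064). Adjusted over the list alone, 25 autophagy, 18 p53, 14 immediate-early, 9 transporter, 10 synthetase and 14 interferon genes fell. On the 8 libraries compared the falls numbered 16, 17, 12, 9, 9 and 12 in that order, with at most 2 rises in each list.

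Nucleolar, mitosis, respiratory chain and nucleotide synthesis lists held more rises than falls with all 12 libraries. Of 28 nucleolar ribosome-making genes 27 rose, with RRS1 at 1.33 and POLR1A at 0.35, but without complete-medium replicates 1 to 3 only 2 rose and 3 fell. Of 26 mitosis and G2/M genes 17 rose, with PLK1 (37.1 ± 22.7 to 76.6 ± 3.95 FPKM) and AURKA (18 ± 12.8 to 37.1 ± 2.16 FPKM). Without the 3 libraries the median of this list went from 0.57 to -0.16. Of 42 nuclear-encoded respiratory chain genes 20 rose, with COX5A at 0.31 and UQCRC2 at 0.50, and without the 3 libraries 16 fell and none rose. Of 18 purine and pyrimidine synthesis enzymes 12 rose and 1 fell, with CAD at 0.48 and CTPS2 at 0.27, against 2 and 2 without them. Of 48 cytosolic ribosomal proteins 5 rose and 4 fell, and 33 fell without the 3 libraries. The median of that list was 0.03 and became -0.07 under quantile normalization, with 6 rises and 20 falls. Of 32 DNA replication genes 9 rose and 9 fell, with TK1 at -0.51 and CDC6 at -0.72. With median-of-ratios scaling 14 rose and 4 fell, the median going from 0.16 to 0.30, and without the 3 libraries 18 fell and none rose, at a median of -0.19. Camera did not call this list (adjusted p = 0.13). Adjusted over the list alone, 28 nucleolar, 20 mitosis, 15 respiratory chain and 12 nucleotide genes rose, and 1 ribosomal protein fell. On the 8 libraries compared 20 nucleolar, 7 mitosis, 10 respiratory chain, 5 nucleotide and 4 replication genes rose. There 1 nucleotide gene, 8 replication genes and 1 ribosomal protein fell, and no ribosomal protein rose.

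Serine and one-carbon genes moved in both directions. Of 17 measured, 5 rose and 7 fell, with AMT at -0.61 and MTHFD2 at -0.47, or 2 and 4 on the 8 libraries compared. With median-of-ratios scaling 5 rose and 2 fell, with quantile normalization 5 and 5, and without complete-medium replicates 1 to 3 the numbers were 1 and 7. The log2 fold change was -0.56 for PSAT1 (SE 0.15, adjusted p = 0.011), -0.33 for PHGDH (SE 0.13, adjusted p = 0.039) and -0.17 for PSPH (SE 0.07, adjusted p = 0.047). For PSAT1 the groups overlapped (exact two-sided permutation p = 0.0857), and with median-of-ratios scaling its change was -0.41 and no longer passed (adjusted p = 0.067). The calls of PHGDH and PSPH were lost on the 8 libraries compared (adjusted p of 0.092 and 0.11) and with median-of-ratios scaling (-0.19 and -0.03). With complete-medium replicates 1 to 3 left out PSAT1 was at -0.74, PHGDH at -0.55 and PSPH at -0.24. SHMT1 was at 0.35 (adjusted p = 0.029) with adjusted p = 0.075 on the 8 libraries, and at -0.04 without complete-medium replicates 1 to 3. SHMT2 was at -0.01 (adjusted p = 0.94) with all libraries and at -0.41 without the 3.

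Among the other lists, 12 of 23 homologous recombination and Fanconi genes fell and 2 rose (EME1 -0.55, FANCG -0.39). With median-of-ratios scaling 6 fell and 3 rose and with quantile normalization 6 and 4, the median going from -0.16 to -0.04 and -0.05. Without the 3 libraries 13 fell and none rose. Of 24 cholesterol genes 7 fell and 3 rose (TM7SF2 -0.91, STARD4 -0.67), against 6 and 6 with median-of-ratios scaling and 13 and none without the 3 libraries. Of 19 fatty acid synthesis genes 8 fell and 4 rose (ACACA 0.70, ACSS2 -0.44), although the median was 0.06. With median-of-ratios scaling or quantile normalization 5 fell and 7 rose, and without the 3 libraries 3 fell and 2 rose. Of 21 NRF2 and glutathione genes 8 fell and 5 rose, with SRXN1 at -0.36, but 4 fell and 8 rose with median-of-ratios scaling, and 9 fell and 3 rose without the 3 libraries. Of 26 glycolysis and hypoxia genes 10 rose and 5 fell, the leading members being ANKRD37 at -0.51 and VEGFA at -0.63. Without the 3 libraries the median of this list went from 0.11 to -0.05. Among 4 measured colon epithelium markers 2 fell and 1 rose (CA2 -0.66, EPHB2 -1.05), and 2 fell and none rose without the 3 libraries. All 4 measured markers of non-epithelial or mesenchymal cells fell, including CD68 at -0.89 and COL1A1 at -0.67, and 1 fell without the 3 libraries. Of 4 histone genes used as a sign of RNA quality 3 rose, with HIST1H2AC at 1.07 and HIST1H2BK at 1.18, or 0.68 and 0.78 without the 3 libraries. On the 8 libraries compared 12 repair, 5 cholesterol, 7 fatty acid, 5 NRF2 and 3 glycolysis genes fell. There 1 cholesterol, 3 fatty acid, 3 NRF2 and 6 glycolysis genes rose.

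**Figure D3:**
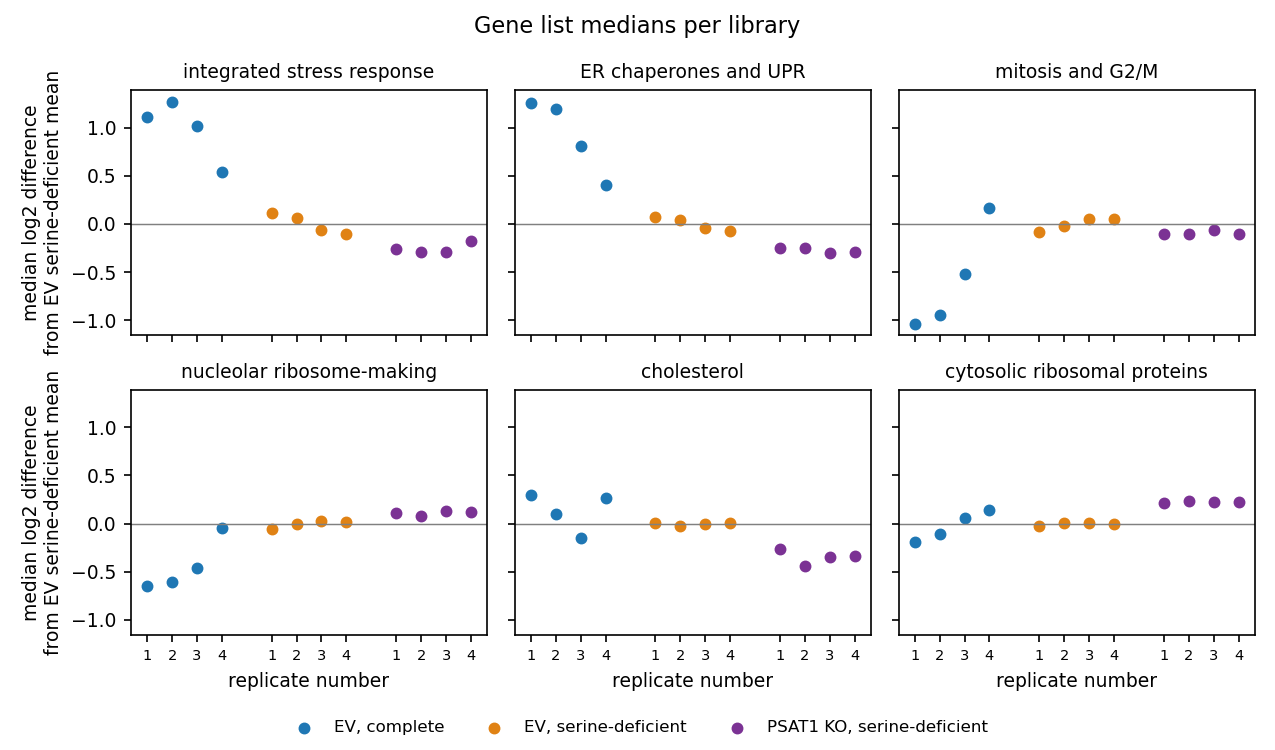
Median over list members of the log2 difference from the EV serine-deficient mean, for 6 gene lists and each of the 12 libraries (dots, coloured by group). Integrated stress response medians lie between 0.54 and 1.27 in the complete-medium libraries, and the mitosis medians there run from -1.04 to 0.16.

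Over all genes, 2366 rose and 4533 fell, 6899 of 11932 tested, with 104 rises and 305 falls of at least 1 on the log2 scale. These last 2 counts were 38 and 166 without complete-medium replicate 1, 52 and 186 without replicate 2, 216 and 654 without replicate 4, and 3 and 11 without replicates 1 to 3. They were 156 and 581 with a pseudocount of 0.1, 42 and 85 with a pseudocount of 5, and 129 and 495 after rescaling to TPM. On the 8 libraries compared the counts were 1614 and 3507. Groups did not overlap for 41.3% of the genes, where chance gives 2.86%. Rises made up 34.3% of the calls, 52.2% with median-of-ratios scaling and 51.4% with quantile normalization, and the median gene was at -0.112 in the FPKM as deposited. Median-of-ratios scaling shifted it by 0.13, so that about as many genes rose as fell relative to the median gene. Camera called 11 of 20 lists, 6 higher and 5 lower than other genes, with adjusted p = 1.9e-05 for the integrated stress response and 5.3e-07 for mitosis. With quantile normalization it called 12, 4 higher and 8 lower. Without complete-medium replicates 1 to 3 it called 15, none higher and 15 lower, and only 4 lists were called the same way in both. None passed with an estimated correlation, where the adjusted p ran from 0.54 to 0.94 and 0 lists had an unadjusted p under 0.05, while fry called 11. Without complete-medium replicates 1 to 3, 1178 genes rose and 1725 fell, and 1892 of the 2903 were also called with all libraries, 1853 in the same direction.

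The second comparison asked what loss of PSAT1 added in serine-deficient medium. Among sterol and fatty acid genes more fell than rose in the knockout cells, and among ribosomal protein genes more rose than fell, with fewer members past the threshold than not in each list. Camera's adjusted p for these lists was 0.47, 0.36 and 0.47 with an estimated correlation. Of 24 cholesterol synthesis and uptake genes 9 fell and none rose (15 fell adjusted over the list alone, median -0.37). MSMO1, an enzyme of sterol synthesis, went from 15 ± 0.379 to 11.7 ± 0.85 FPKM (log2 fold change -0.33, SE 0.06, adjusted p = 0.0098). Of 19 fatty acid synthesis genes 5 fell (9 fell and 1 rose adjusted over the list alone). These included FADS1, a fatty acid desaturase, at -0.46, and SREBF1, a transcription factor of lipid synthesis, at -0.42. The other members that fell, named after their values were seen, were FASN (-0.66), LPIN1 (-0.63) and ACSL3 (-0.39). On the 8 libraries compared 20 cholesterol genes fell, and 13 fatty acid genes fell and 1 rose. With single libraries left out, 2 to 18 cholesterol genes and 1 to 12 fatty acid genes fell, with list medians from -0.41 to -0.30 and from -0.22 to -0.19. The 18 and 12 came without complete-medium replicate 4, the 2 without EV serine-deficient replicate 1 or knockout replicate 3, and the 1 without any single EV serine-deficient library or knockout replicate 3 or 4.

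Of 48 cytosolic ribosomal proteins 14 rose and none fell (30 adjusted over the list alone, median 0.22). RPL28 went from 464 ± 4.42 to 542 ± 9.41 FPKM (log2 fold change 0.22, SE 0.04, adjusted p = 0.0094) and RPL12 from 1010 ± 6.22 to 1220 ± 22.9 FPKM (0.27, SE 0.06). In EV cells in complete medium RPL28 stood at 547 ± 10.7 FPKM, near its knockout level. RPL12 stood there at 973 to 1130 FPKM, below all knockout libraries. On the 8 libraries compared 45 rose. With quantile normalization the median was 0.06, with 6 rises and 2 falls, and with median-of-ratios scaling it was 0.30, with 5 rises. Leaving out any single EV serine-deficient library, or knockout replicate 3 or 4, left 1 rise, at medians of 0.21 to 0.22. Without knockout replicates 1 and 2 in turn 4 and 5 rose, whereas 27 and 37 rose without complete-medium replicates 1 and 4. Genes of this family share sequence with many pseudogenes, so single members are uncertain.

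**Figure D4:**
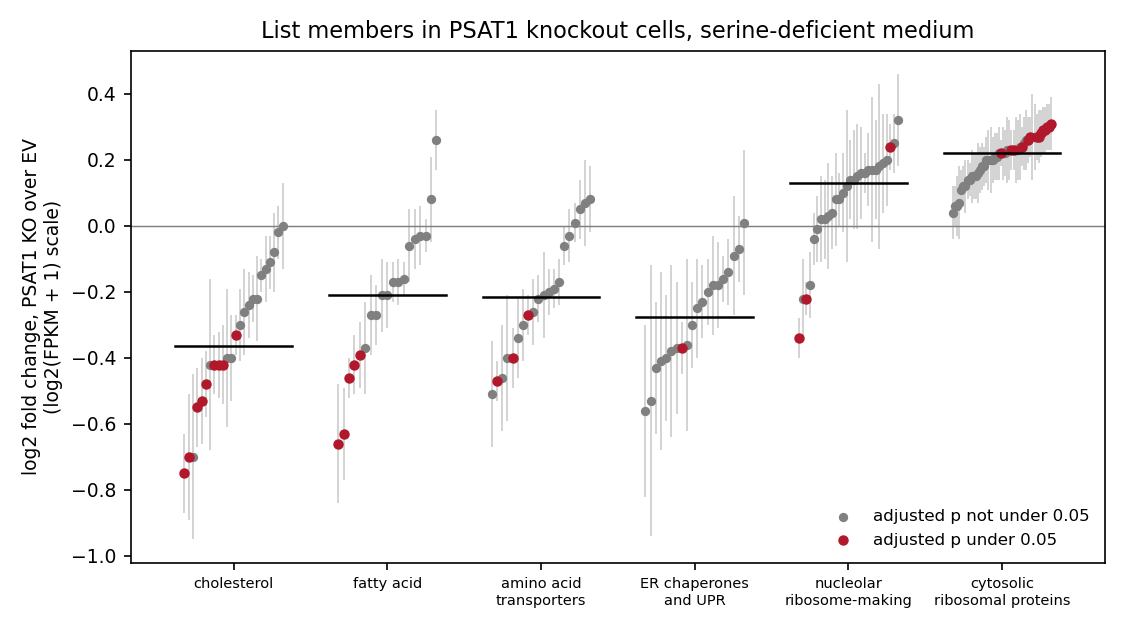
Log2 fold change of each measured member of 6 gene lists, knockout over EV in serine-deficient medium, with its SE (grey lines) and the list median (black line). Red dots passed an adjusted p of 0.05 in the 12-library fit, 9 of 24 in the cholesterol list and 14 of 48 among ribosomal proteins.

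Of 20 amino acid transporters 3 fell (11 adjusted over the list alone). They were SLC7A5, a carrier of large neutral amino acids, from 220 ± 14.4 to 159 ± 8.67 FPKM (-0.47), SLC7A1 at -0.27 and, named after its values were seen, SLC7A8 at -0.40. Of 20 endoplasmic reticulum chaperone genes 1 fell, SDF2L1 at -0.37, although the list median was -0.28 and 17 fell on the 8 libraries compared. Of 22 integrated stress response genes 1 fell, PYCR1 at -0.25, and 14 fell and 2 rose on the 8 libraries. Among serine and one-carbon genes PSAT1 and PSPH fell, PSPH from 16.6 ± 0.61 to 13.6 ± 0.311 FPKM (log2 fold change -0.27, SE 0.07, adjusted p = 0.03, lost with median-of-ratios scaling at -0.19 and with quantile normalization at -0.21). PHGDH stood at 59.1 ± 4.44 and 71.6 ± 2.45 FPKM (0.27, SE 0.13, adjusted p = 0.19, or 0.0012 on the 8 libraries). SHMT1 (-0.16, adjusted p = 0.45) and SHMT2 (0.10, adjusted p = 0.7) did not pass.

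The largest rise was that of LCN2, an iron-binding secreted protein, from 16.4 ± 2.18 to 39.8 ± 2.02 FPKM (log2 fold change 1.24, SE 0.23, adjusted p = 0.009). In EV cells in complete medium LCN2 stood at 28.6, 32.7, 50.4 and 17.9 FPKM, a range that holds its knockout level. The next rises were those of MT2A, a metallothionein, from 488 ± 60.1 to 810 ± 43 FPKM (0.74), SNHG21 (0.61), HIST1H2BK (0.57), IGBP1P1 (0.57) and KLK7 (0.56). Large falls besides that of PSAT1 were those of P2RY11 (-1.14), DHRS2 (-0.81), PVRIG2P (-0.76) and TGFB1 (-0.74), which went from 24.3 ± 0.791 to 14.1 ± 1.67 FPKM. With length and GC trends removed MT2A, IGBP1P1 and P2RY11 no longer passed (adjusted p of 0.054, 0.098 and 0.055). MT2A went from 0.74 (SE 0.20) to 0.79 (SE 0.20) and its unadjusted p from 0.0036 to 0.002, so its call ended because fewer genes passed and the adjustment became stricter. IGBP1P1 went from 0.57 (SE 0.15) to 0.47 (SE 0.15) and P2RY11 from -1.14 (SE 0.24) to -0.96 (SE 0.24), with unadjusted p of 0.008 and 0.0022.

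In the remaining lists few members passed in the 12-library fit, and most of those named here lost their call once length and GC trends were removed. DARS (0.24) rose among the tRNA synthetases, NDUFS1 (0.25) among respiratory chain genes, and PLK2, a p53 target, from 40.9 ± 0.405 to 60.5 ± 0.651 FPKM (0.55). CAD (-0.43) and IMPDH1 (-0.24) fell among nucleotide enzymes, although the list median was 0.12 and on the 8 libraries compared 11 rose and 4 fell. Further falls were those of POLE (-0.30) and E2F2 (-0.21) among replication genes, XRCC3 (-0.29) among repair genes, and HK1 (-0.17) and PFKL (-0.19) among glycolysis genes. GSS (0.19) rose in the NRF2 and glutathione list, and OAS3 (-0.27) fell among interferon-stimulated genes. In the autophagy and lysosome list 2 fell and 2 rose, with CTSD at -0.28 and ATG12 at 0.30. Of the nucleolar genes 2 fell, POLR1A at -0.34 and RRP12 at -0.22, and 1 rose, while the list median was 0.13 and on the 8 libraries 16 rose and 4 fell. Camera placed the nucleotide and nucleolar lists higher than other genes (adjusted p of 0.034 and 0.015, or 0.98 for both with an estimated correlation). On the 8 libraries 9 synthetases rose and 2 fell, 19 respiratory chain genes rose, 10 replication genes rose and 9 fell, and 3 repair genes rose and 6 fell. There 4 p53 targets rose and 10 fell, and the numbers were 4 and 13 for glycolysis, 6 and 9 for the NRF2 list, 3 and 9 for the interferon list and 5 and 11 for autophagy. No mitosis gene and no immediate-early gene passed with limma, with medians of -0.08 and -0.14, and 12 and 8 fell on the 8 libraries compared. No colon epithelium marker passed, though 3 of 4 fell on the 8 libraries, and 1 of 4 non-epithelial markers fell, COL1A1 at -0.68. Of 4 histone genes 3 rose, including HIST1H2BD (0.53) and HIST1H2AC (0.46). With length and GC trends removed PLK2, CAD, XRCC3, GSS and OAS3 still passed. The values were then 0.10 for DARS, 0.18 for NDUFS1, -0.10 for IMPDH1, -0.13 for POLE, -0.06 for E2F2, -0.13 for HK1 and -0.01 for PFKL. They were -0.14 for CTSD, 0.21 for ATG12, -0.12 for RRP12, -0.50 for COL1A1, 0.45 for HIST1H2BD and 0.35 for HIST1H2AC. None of these 13 passed (adjusted p from 0.059 to 0.94), and their SE ran from 0.04 to 0.13, against 0.04 to 0.16 before.

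Over all genes, 265 rose and 917 fell, 1182 of 11932. On the 8 libraries compared 2021 rose and 4288 fell, and all 1182 were among these 6309. Only 1 rise and 2 falls reached 1 on the log2 scale, or 1 and 10 with a pseudocount of 0.1, 1 and 6 after rescaling to TPM and 3 and 3 on the 8 libraries. Groups did not overlap for 48.8% of the genes, against 2.86% by chance. Rises made up 22.4% of the calls, 10.1% after rescaling to TPM, 49.5% with median-of-ratios scaling and 45% with quantile normalization. Camera called 9 of 20 lists, 5 higher and 4 lower, with adjusted p = 1.4e-22 for ribosomal proteins, 8.7e-06 for cholesterol and 0.0044 for fatty acid synthesis. With quantile normalization it called 7 lists, 1 higher and 6 lower, of which 5 were called the same way in both. None passed with an estimated correlation, where the adjusted p ran from 0.36 to 0.98 and 2 lists had an unadjusted p under 0.05, while fry called 3. Across genes the fold changes went with GC content (Spearman -0.48), and length and GC trends took up 26.5% of their variance, against 1.05% for the medium comparison. With these trends removed 75 genes rose and 317 fell, and 23 of the 43 genes that the naming rule took for this comparison no longer passed, among them SREBF1 (adjusted p = 0.088), SLC7A1 (0.14), SDF2L1 (0.079), PYCR1 (0.07) and POLR1A (0.25). In 22 of the 23 the log2 fold change became smaller, with a median ratio of 0.67 to that before and of 0.98 for the SE. SREBF1 went from -0.42 (SE 0.09) to -0.30 (SE 0.09), SLC7A1 from -0.27 (SE 0.06) to -0.17 (SE 0.06) and SDF2L1 from -0.37 (SE 0.08) to -0.25 (SE 0.07). PYCR1 went from -0.25 (SE 0.05) to -0.16 (SE 0.04) and POLR1A from -0.34 (SE 0.06) to -0.21 (SE 0.09). PSAT1, LCN2, PLK2, MSMO1, FADS1, SLC7A5, RPL28 and RPL12 still passed, and 8 cholesterol genes, 3 fatty acid genes and 9 ribosomal proteins were called.

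The third comparison set knockout cells in serine-deficient medium against EV cells in complete medium, so that medium and genotype both differed. In total 2437 genes rose and 5800 fell, and 1455 rose and 3653 fell without complete-medium replicates 1 to 3. Rises were 29.6% of the calls and 52.8% with median-of-ratios scaling and 51.6% with quantile normalization. All 20 endoplasmic reticulum chaperone genes fell, as did 18 of 22 integrated stress response genes and 17 of 24 cholesterol genes, and without the 3 libraries 18, 18 and 23 fell. PSAT1 was at -1.58 (SE 0.15, adjusted p = 3.1e-05) and PSPH at -0.44 (adjusted p = 0.00034), while PHGDH (-0.06), SHMT1 (0.19) and SHMT2 (0.09) did not pass. Without complete-medium replicates 1 to 3 PHGDH was at -0.27, SHMT1 at -0.20 and SHMT2 at -0.32.

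The medium and knockout effects were also compared across genes, which are not independent replicates. Their Pearson correlation was 0.207 and Spearman correlation 0.242. Both contrasts use the EV serine-deficient libraries with opposite sign, and simulated unchanged groups gave -0.257 and -0.148. The simulated noise was independent between genes, so spread that genes share is not covered by these values. The covariance was 0.018 against -0.005 in simulation, a difference of 0.022. When the shared libraries were split, the Pearson correlation averaged 0.240 over 6 splits, from 0.122 to 0.347. Genes that fell in both numbered 244, genes that rose with the medium and fell with the knockout 206, genes that rose in both 59, and genes that fell with the medium and rose with the knockout 62. Independent lists of the same sizes give 348, 182, 53 and 101, and simulated unchanged groups 0, 0.04, 0 and 0. The first figures leave out the shared libraries and the second the effects, so neither sets a mark for the observed counts. With the shared libraries split, which leaves fewer in each contrast, the means were 19.3, 11.2, 4.7 and 1.0.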

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

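All tests of explanations in this part were chosen after the results had been seen. Single libraries far from the other 3 of their group were sought among the named genes and the numbers of genes at 0. Of 282 groups of 4, 22 held such a library, where chance gives about 14 if the groups are independent. They are not, since all genes were read in the same 12 libraries, so no excess over chance can be read from these counts.

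In the complete-medium group replicate 4 was the library apart for SLC3A2 (179 FPKM), AARS (130), CDC6 (51.1), SLC7A5 (265) and E2F2 (6.36), each below the others, and for ACACA (21.5), COX5A (107), POLR1A (15.3), NDUFS1 (20.1) and RRP12 (19), each above. In the EV serine-deficient group it was SHMT2 (73.3 FPKM, replicate 1), EME1 (8.96, replicate 3), IFI35 (7.36, replicate 4) and CD68 (5.09, replicate 4), all lower than the rest, and replicate 1 had 49 genes at 0 against 41 to 42. In the knockout group it was SLC43A1 (0.968 FPKM, replicate 3), CAD (30.3, replicate 1), COX5A (117, replicate 4), POLR1A (13.6, replicate 4), HIST1H2BK (27.3, replicate 2) and RRP12 (18.8, replicate 4). Knockout replicate 2 had 116 genes at 0 against 35 to 43 in the other knockout libraries, and 61 of its zeros were above 0 in all 3 others.

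The spread of the complete-medium libraries was the first pattern weighed. On an axis running from 0 for complete-medium replicate 1 to 1 for replicate 4, replicates 2 and 3 lay at 0.128 and 0.556 and the EV serine-deficient libraries between 0.979 and 1.06. A steady drift along the library code would need like steps in the later codes, and the change over the serine-deficient codes was 0.081 of that over the complete-medium codes. This speaks only to a drift of equal steps. In the order of the codes the first principal component rose throughout. It ran through -61.29, -55.18, -28.44 and 3.03 in complete medium and 8.455, 10.93, 14.66 and 15.52 in serine-deficient medium, as a drift that slows would also give. Length and GC trends took up 4.4% of the variance of the difference between replicates 4 and 1. An exchange with a single serine-deficient library lacks a partner, since the lowest of these scored 0.979. That score cannot address an exchange of the whole complete-medium and serine-deficient groups of EV cells. A difference in culture state or handling, a drift that slows along the codes, or a step between codes stays open. No label settles which, and no biological explanation was tested.

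The second pattern was the lower sterol and fatty acid genes of the knockout libraries. Over the 43 members of both lists the median was -0.27. It was -0.27 with length and GC trends removed, -0.30 with the complete-medium axis removed by regression over genes and -0.23 with quantile normalization, so none of these can be the whole cause. Loss of PSAT1 may lower these genes, as a hypothesis. Differences between the edited and control cells apart from PSAT1, and a library batch, remain open because knockout and EV libraries are labelled by different title schemes and cannot be separated from genotype.

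The third pattern was the higher ribosomal protein genes, whose median of 0.22 over 48 members became 0.16 with length and GC trends removed, 0.17 with the axis removed and 0.06 with quantile normalization, where 6 rose and 2 fell. The trends with length, GC and the axis thus account for part of the shift at most. Quantile normalization gives every library 1 distribution and so takes out much of any shift of the most abundant genes, and 43 of the 48 members were among the 200 most abundant genes. Unequal distributions of values and a change in the cells therefore cannot be told apart for this list. The same differences between cell populations and library batches stay open, and an effect of the knockout is a hypothesis.

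Other splits of the same 8 libraries were counted for each comparison. The real split gave the most calls of 35 in each (1 of 35), the smallest share that this count can give. It cannot show whether new cultures would differ likewise, since the replicates may be technical. For the medium it gave 6899 genes and the highest other 6169, for the knockout 1182 and 1, and for the third comparison 8237 and 5390. The splits giving 6169 and 5390 set complete-medium replicates 1 to 3 and 1 other library against the rest, which points to the structure of that group.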

How the results depend on the processing

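The fit without complete-medium replicates 1 to 3, the length and GC correction and the library code covariate were chosen after seeing the data. For single genes 2534 values kept direction and side of the threshold, 289 no longer passed, 10 newly passed and 3 reversed. For the lists that camera called in the main fit, 11 for the medium and 9 for the knockout, 479 values were the same, 55 no longer past the threshold and 6 reversed. Other lists were not counted, though medians of some changed sign. With median-of-ratios scaling the medium median went from -0.01 to 0.13 for NRF2 genes and from -0.02 to 0.09 for serine and one-carbon genes. Except where stated, the cause was not tested.

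Counts of changed genes of any size moved by over 1.5 times as follows. For the knockout, 6309 genes were called on the 2 groups compared and 6309 without complete-medium replicates 1 to 3, since the wide spread of those libraries then no longer enters. Removing length and GC trends left 392, and 5828 genes had groups without overlap. At an adjusted p of 0.01, 3846 genes passed for the medium and 272 for the knockout. Without complete-medium replicates 1 to 3 the medium gave 2903 and the third comparison 5108. With the library code as a linear covariate in the EV libraries limma called 0 genes, with a lowest adjusted p of 0.69. Of 11932 genes tested 714 had an unadjusted p under 0.05, and the median SE was 0.17 against 0.1. Every serine-deficient library has a higher code than every complete-medium one, so code and medium overlap strongly, though the code also varies within each medium. The medium calls thus did not hold once a linear trend with the code was allowed. This fit cannot show whether medium or code underlies them. Leaving out each library in turn gave 347 to 3255 genes for the knockout. The highest came without complete-medium replicate 4, followed by 1814 without replicate 1. Without single EV serine-deficient libraries 351, 353, 451 and 529 were called, and without single knockout libraries 640, 721, 347 and 453. Of the 12 fits that leave out a library, the medium call was lost in 9 for PHGDH and in 11 for PSPH, and the knockout call of PSPH in 8. Of 43 knockout calls of named genes, leaving out EV serine-deficient replicates 1 to 4 in turn ended 24, 24, 23 and 20, knockout replicates 1 to 4 ended 15, 16, 22 and 21, and complete-medium replicates 1 to 4 ended 0, 2, 2 and 0. Median-of-ratios scaling ended 13 and quantile normalization 15.

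Counts of changes of at least 1 on the log2 scale moved too. For the medium 409 became 14 without complete-medium replicates 1 to 3, 204 to 870 with single libraries left out, 737 and 127 with pseudocounts of 0.1 and 5, 624 after rescaling to TPM and 269 with a mean FPKM of at least 5. For the third comparison 768 became 64 without those 3 libraries, 477 to 1322 with single libraries left out, 1323 and 211 with the 2 pseudocounts, 1232 after rescaling to TPM and 455 with a mean FPKM of at least 5.

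With an estimated correlation camera called 0 lists for the medium and 0 for the knockout, and fry called 3 for the knockout. PSAT1 with median-of-ratios scaling was at -0.41 for the medium and no longer passed. The Pearson correlation of medium and knockout effects was 0.114 with quantile normalization. The medium median of the ribosomal proteins reversed to -0.07 with quantile normalization. Without complete-medium replicates 1 to 3, medium medians reversed for mitosis (-0.16), purine and pyrimidine enzymes (-0.06), glycolysis (-0.05), the respiratory chain (-0.14) and ribosomal proteins (-0.14). The same held for DNA replication (-0.19) and fatty acid synthesis (-0.09), which camera had not called. SHMT1 also reversed for the medium (-0.04), as did SHMT1 (-0.20) and SHMT2 (-0.32) in the third comparison.

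Replicate numbers were not taken to pair the libraries, a choice fixed beforehand because the labels do not say what a number shares. Structure shared by number remains possible, above all for the medium. Correlations of same-numbered deviations ran from 0.09 to 0.26 for the medium, where 7 of 8 libraries went best with their own number, from -0.03 to 0.41 for the knockout (4 of 8) and from -0.09 to 0.01 for the third comparison (0 of 8). With the replicate block 6722, 862 and 8050 genes were called. Depth per library is unknown, so precision of low genes cannot be given.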

Other observations

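The gene groups in this part were listed after the main results had been seen, and genes named here were chosen after their values were seen. Metallothioneins, which bind zinc and copper, differed between groups. MT1E went from 87.6 FPKM in complete to 243 FPKM in serine-deficient medium (log2 fold change 1.62, SE 0.30, limma adjusted p = 0.002) and stood at 447 FPKM in the knockout cells. MT1X went from 18.3 to 37.8 FPKM (1.11) and stood at 62.6 FPKM in the knockout, and MT2A from 281 to 488 FPKM (0.85). The other measured member, MT1F, fell from 5.71 to 3.64 FPKM (-0.53, adjusted p = 0.034). Without complete-medium replicates 1 to 3 the changes of MT1E, MT1X and MT2A with the medium were 0.67, 0.44 and 0.43, and that of MT1F was -0.28. Against EV cells in the same medium only MT2A passed in the 12-library fit (adjusted p = 0.042), while MT1E, MT1X and MT2A passed on the 8 libraries (4.7e-05, 7.3e-05 and 7e-05). The median of the 4 measured genes was 0.73 and stayed at 0.73 with length and GC trends removed. The family shares sequence.

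Of 13 cytosolic and mitochondrial heat shock proteins 8 rose with serine-deficient medium and 2 fell, with a median of 0.28 and a camera adjusted p of 0.0015, or 0.26 with an estimated correlation. HSPA8, in the cytosol, went from 642 to 1160 FPKM (0.90), HSPE1, in mitochondria, from 104 to 209 FPKM (1.23), and DNAJB1 from 133 to 92 FPKM (-0.49). Without the 3 libraries 5 rose and 2 fell, at a median of 0.05, with HSPA8 at 0.34, HSPE1 at 0.05 and HSP90AA1 at -0.34. In the knockout 3 fell, HSPA1A (-0.45), HSPA1B (-0.51) and BAG3 (-0.28). Of 28 mitochondrial ribosomal proteins 10 rose with the medium (camera adjusted p = 0.32 with an estimated correlation, and 2 rose and 1 fell without the 3 libraries) and none in the knockout, where 14 rose on the 8 libraries compared. Of 18 genes that host small nucleolar RNAs 5 rose in the knockout and none fell, with a median of 0.22, and camera's adjusted p was 1.4e-07 and 0.0052 with an estimated correlation. GAS5 went from 58.7 to 93.2 FPKM (0.66, adjusted p = 0.059, or 6.7e-06 on the 8 libraries). It stood at 114 FPKM in complete medium and fell with the medium (-0.87, limma adjusted p = 0.0049), or by -0.17 without the 3 libraries.

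Host genes of small nucleolar RNAs and ribosomal proteins share a start sequence, the terminal oligopyrimidine tract, that ties translation to growth signals. The hypothesis was that transcripts with this tract move together in the knockout. The test, set before its result was seen, was whether 18 translation factors with the tract were higher too, with a median of at least 0.5 times the 0.22 of the ribosomal proteins. Their median was 0.20 (bootstrap spread 0.028), 6 rose and none fell, and 15 rose on the 8 libraries. Camera's adjusted p was 2.7e-09, and 0.19 with an estimated correlation. The median was 0.12 with length and GC trends removed, against 0.16 for the ribosomal proteins, and 0.10 with quantile normalization, against 0.06. The test was met on the values as deposited, while the 0.10 with quantile normalization fell short of 0.5 times 0.22. Knockout fold changes also went with the mean level of a gene (Spearman 0.28), and no equally abundant genes without the tract were compared. The test therefore cannot tell a shared change of such transcripts from a shift of abundant genes. Either may follow from the knockout or from differences between the cell populations that the design does not separate.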
